A study of Mus musculus with 16 samples.

How the data were processed

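Genomic DNA of mouse embryonic stem cells was bisulfite converted, a LINE1 amplicon was produced by PCR with LINE1 primers, and the products were sequenced, per the labels' protocols. Bisulfite turns unmethylated C into a base read as T, so the share of C among C and T calls at a CpG estimates its methylation. There were 16 libraries, 4 for each of wtJ1, Uhrf1 KO, H730A and F46A, and group and replicate number were taken from the sample titles. The series describes them as biological replicates, but whether they came from separate clones or cultures is not given in the sources used here. Permutation p-values therefore measure the spread between these samples.

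Each deposited file lists CpG sites of 1 library by chromosome, position and strand, with the count of calls read as C and the count of calls read as C or T, per the file headers. The deposited ratio is a fraction from 0 to 1 per site, equal to the count of C divided by the total, per the file headers. Trim Galore 0.3.1, BSMAP 2.90, methylKit and the genome build mm10 are named in the submitters' processing notes, without their roles. The files hold CpG context alone, so the conversion rate could not be estimated from them, and reverse-strand counts used to remove variants are 0 in every line. How reads that match several LINE1 copies were placed is not given in the sources used here. LINE1 copies are near-identical, so the assignment of a value to a single copy or host gene is uncertain. Pooled levels need no such assignment, but which sites reach the minimum coverage can depend on it, and this was not tested.

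Counts were used as deposited. A site was tested when it had at least 10 calls in all 16 libraries. The level of a library is the sum of methylated calls divided by the sum of calls over these sites, in percent. Neighbouring sites on 1 strand with gaps of at most 200 bp formed a copy. The most common pattern of CpG distances, found in 125 copies, served as the amplicon template, extended by positions seen in at least 30 copies, and a unit needed at least 6 sites on the template. This gave 849 units with 15 positions, 10059 sites on the template and 126 off it. Host genes came from the RefSeq gene table of GRCm38.p6, the assembly behind mm10, by span alone, for protein-coding and lncRNA genes. Exons, introns and UTRs were not annotated here.

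Group levels were compared by an exact two-sided permutation test of the difference of means, with Benjamini-Hochberg adjustment over the 3 comparisons with wtJ1 and, separately, the 3 between mutants. The smallest p for 4 against 4 is 0.0286 and for 3 against 4 it is 0.0571. Intervals are 95% and come from inverting the same test. Per site, a quasi-binomial model on the 8 libraries of a comparison was used, with Pearson dispersion moderated by limma's squeezeVar, not allowed below 1, and Benjamini-Hochberg adjustment at 0.05 over sites. The median dispersion was 1 in every comparison but F46A against H730A (1.04), so many site p-values rest on counting error. Fisher's exact and chi-square tests hold no spread between samples. Replicates 1 and 2 of wtJ1 were averaged as 1 sample in means and SDs, and a fit with their calls summed was added after the data were seen. Overlaps of calls were set beside independent lists, 20 simulations of unchanged groups and splits of the wtJ1 libraries.

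The site model was tested on simulated data with 300 changed among 10185 sites, in 3 sizes of 100 sites. For Uhrf1 KO against wtJ1 it recovered 0, 34 and 92% of sites changed by -10, -20 and -40 points, with median estimates of -9.68, -19.9 and -39.4 points, and for H730A against Uhrf1 KO 14, 64 and 96% of sites changed by 8, 20 and 40 points. It called 0 unchanged sites, and 2.80 and 2.28% of them had an unadjusted p under 0.05. For Uhrf1 KO against wtJ1 the changed sites were drawn only from sites well above the upper quartile of wtJ1 levels (31.6%). In the data most sites changed, with a median difference of -20.0 points and 9591 of 10185 called. The simulated shares therefore do not measure recovery in the data.

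Sites named in the text were chosen by a rule set before the data were examined, unless marked as named after their values were seen. The main tests, the gene lists and most alternatives were also set before the data were examined. Sites past adjusted p 0.05, with at least 30 calls in every library of both groups and no overlap between the groups' libraries, were ranked by difference, taking 1 per 1000 bp. The first 8 were named against wtJ1, with up to 4 in the opposite direction, and the first 4 between mutants, of which 1 site is not reported here. For gene lists the 2 genes with the most calls were named. The alternatives were coverage minimums of 30 and 100 calls, all sites with 10 calls in that library, unweighted means, removal of the top 0.1% of coverage, single strands, thinning to 10 calls, each replicate left out, the replicate number as a block, limma on logit values with an offset of 0.5, Fisher's exact test, 1 fit of all 16 libraries, 1 site per 1000 bp, and a threshold of adjusted p 0.01 with 25 points. Added after the data were seen were the tests by amplicon position, calls summed per copy, equal weight per copy or position, all listed sites, and leaving out position 1 and sites off the template. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.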

Results

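LINE1 elements are retrotransposons present in very many copies in the mouse genome, and their CpG methylation serves as a readout of methylation across many loci at once. A LINE1 amplicon was measured by bisulfite PCR and sequencing in mouse embryonic stem cells of 4 genotypes, grown in serum with LIF and the 2i inhibitors. The genotypes were J1 wild-type cells (wtJ1), a Uhrf1 knockout (Uhrf1 KO), and the Uhrf1 point mutants H730A and F46A. UHRF1 binds hemimethylated DNA after replication, ubiquitinates histone H3 and recruits the maintenance methyltransferase DNMT1. The series concerns the ubiquitin-like (UBL) domain of UHRF1 and its E3 ligase activity, and as background F46A lies in the UBL domain and H730A in the RING domain that carries the ligase activity. Each genotype had 4 libraries, described as biological replicates. The amplicon holds no part of Uhrf1, so the genotypes were taken from the labels and not checked in the reads.

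Each library held between 998982 and 1287040 CpG calls. Of 49722 CpG sites listed in any library, 10185 had at least 10 calls in all 16 libraries, and these held 89.8% of all calls. The median coverage of a tested site was between 57 and 73 calls per library. The tested sites fell into 753 stretches of CpG sites on one strand, called copies here. Of these, 214 lay in an annotated gene, 539 outside genes and 99 on the X chromosome. The 10 deepest copies held 13.7% and the 100 deepest 50.1% of the calls at tested sites. Calls are PCR reads without molecular identifiers, so their number covers counting error only.

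In chi-square tests of coverage per copy, calls per copy and calls per amplicon position, wtJ1 replicates 1 and 2 did not differ beyond sampling noise (p = 0.259, 0.743 and 0.317). The other pairs of wtJ1 libraries differed by position, past sampling noise in the same test. Every pair within the other genotypes differed in at least 1 of these measures. The p-values were not adjusted. Uhrf1 KO replicates 1 and 4 differed in coverage alone (chi-square p = 0.0281). In calls per copy no pair of wtJ1 or of Uhrf1 KO libraries differed past sampling noise. The files of wtJ1 replicates 1 and 2 are not identical, and they may be no more than close replicates. As a cautious choice they were counted as 1 sample in means and SDs, which gives n = 3 for wtJ1 and n = 4 for the other genotypes. Tests used the 4 libraries as planned, and values with wtJ1 counted as 3 are given beside the levels.

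Loss of UHRF1 removed most LINE1 methylation. The level was 24.9% ± 0.353 (SD, n = 3) in wtJ1 and 4.95% ± 0.0695 (SD, n = 4) in Uhrf1 KO, so the knockout kept 19.9% of the wild-type level. The difference was -19.8 percentage points with a 95% interval from -20.3 to -19.4, and every Uhrf1 KO library lay below every wtJ1 library (exact two-sided permutation test, p = 0.0286, adjusted p = 0.0286 over 3 comparisons). With wtJ1 counted as 3 samples the difference was -19.9 points and the exact p was 0.0571, the smallest that 3 against 4 allows, so this count cannot pass 0.05. Both point mutants were depleted as well. H730A was at 7.45% ± 0.872 (SD, n = 4), 29.9% of the wild-type level, and F46A was at 5.40% ± 0.943 (SD, n = 4), 21.7% of it. H730A differed from wtJ1 by -17.3 points (95% interval -18.7 to -15.8) and F46A by -19.4 points (95% interval -20.9 to -17.9), each with an exact permutation p of 0.0286 and an adjusted p of 0.0286. Counting wtJ1 as 3 samples gave -17.4 and -19.5 points, each with an exact p of 0.0571.

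**Figure D1:**
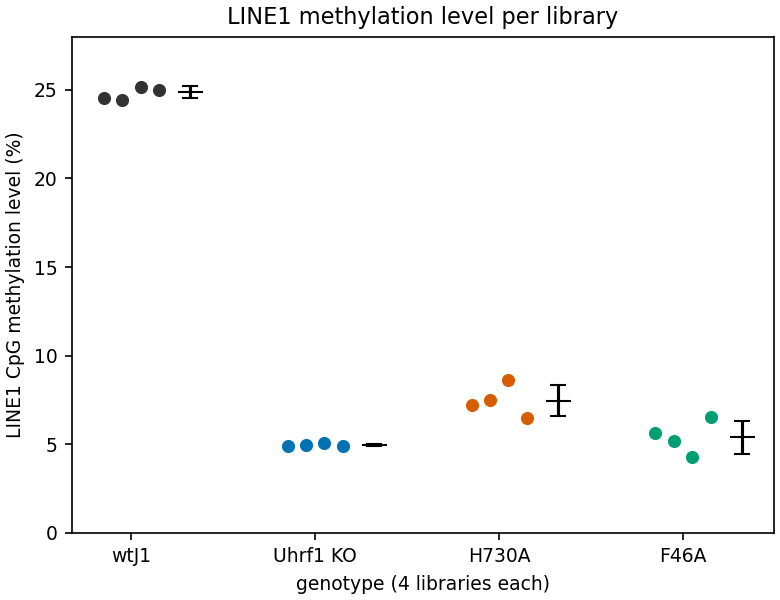
LINE1 CpG methylation level in percent (y axis) for each of the 16 libraries, grouped by genotype (x axis). With means ± SD beside the points (n = 3 for wtJ1, n = 4 for the others), wtJ1 libraries sit between 24.4 and 25.2%, Uhrf1 KO between 4.90 and 5.04%, H730A between 6.51 and 8.60% and F46A between 4.27 and 6.53%.

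The loss reached nearly every CpG site and each of the 753 copies. In Uhrf1 KO 9591 of the 10185 tested sites were lower than in wtJ1 and 0 were higher (quasi-binomial model per site with limma's moderated dispersion, adjusted p under 0.05). By the same test 9307 sites were lower and 2 higher in H730A, and 9623 were lower and 2 higher in F46A. With calls summed per copy, all 753 copies were lower in each of the 3 mutant genotypes. The median copy was at 25.3% in wtJ1, 4.95% in Uhrf1 KO, 7.54% in H730A and 5.36% in F46A. Copies with more methylation in wild type kept more in the mutants. The copies were split into 4 classes of nearly equal size by their level in wtJ1 replicates 1 and 2. From the lowest to the highest class the level in wtJ1 replicates 3 and 4 went from 18.9 to 32.1%. Across these classes Uhrf1 KO went from 4.36% ± 0.0458 to 5.83% ± 0.112, H730A from 5.75% ± 0.761 to 10.1% ± 1.09, and F46A from 4.56% ± 0.864 to 6.66% ± 1.09 (SD, n = 4). As a share of wild type this is 23.1 against 18.1% in Uhrf1 KO, 30.5 against 31.4% in H730A and 24.1 against 20.8% in F46A.

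**Figure D2:**
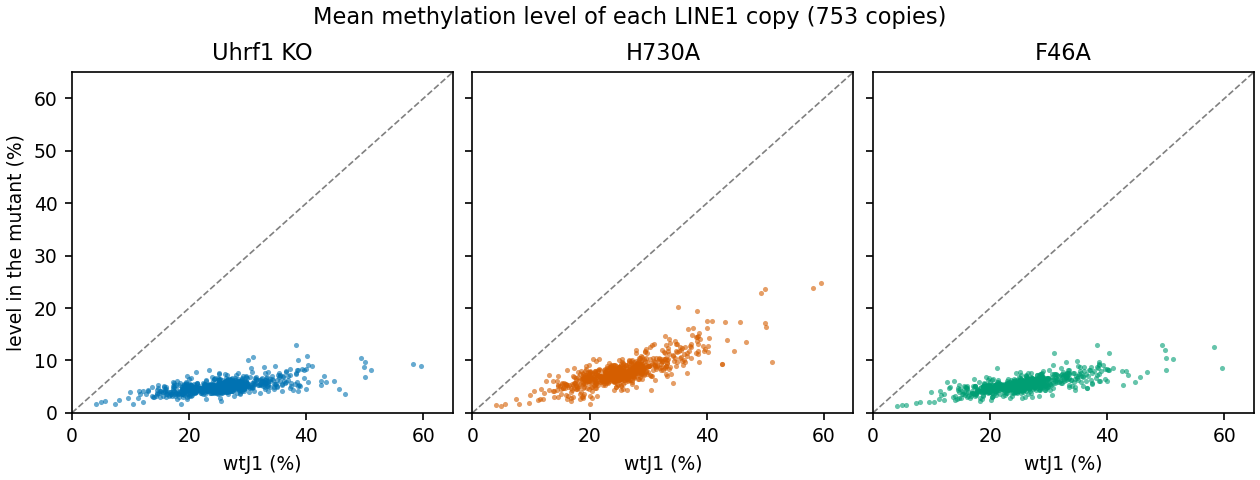
Mean methylation level in percent of each of the 753 LINE1 copies in wtJ1 (x axis) against Uhrf1 KO, H730A and F46A (y axis, one panel each). The dashed line marks equal levels, and every copy lies below it in all 3 panels.

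The named sites with the largest losses were highly methylated in wild type, which ranking by percentage points requires. Site differences use calls summed over the 4 libraries of each genotype, and need not equal those between the means shown. At chr1:150233242 (mm10, outside annotated genes) the level was 73.4% ± 4.87 in wtJ1 (SD, n = 3), 2.92% ± 3.46 in Uhrf1 KO, 40.2% ± 7.22 in H730A and 8.20% ± 4.87 in F46A (SD, n = 4), from 40 to 66 calls per library of wtJ1 and Uhrf1 KO. Among sites that met the naming rule it had the largest difference in Uhrf1 KO, -68.8 points (adjusted p = 1.82e-07), and in F46A, -64.3 points (adjusted p = 3.69e-07), in the quasi-binomial model fitted to all tested sites with limma's moderated dispersion. The site at chr2:23940173 went from 81.4% ± 3.28 in wtJ1 to 15.7% ± 8.42 in Uhrf1 KO, 49.2% ± 3.39 in H730A and 24.0% ± 5.64 in F46A. The site at chr14:22835631 lies in the span of the protein-coding gene Lrmda and was among the 8 named losses of all 3 mutants, from 62.5% ± 5.21 in wtJ1 to 2.16% ± 4.31 in Uhrf1 KO, 12.2% ± 7.40 in H730A and 8.19% ± 2.61 in F46A. Sites at chr6:18586400 and chr3:81712267 were also in all 3 lists, with 56.9% ± 5.32 and 60.9% ± 5.51 in wtJ1 and at most 14.1% in any mutant. The copy at chr13:62420030 to 62420172 held a named site in each list, among them position 62420135, which fell from 67.4% ± 0.997 in wtJ1 to 4.65% ± 3.08 in Uhrf1 KO. The largest named loss in H730A was at chr13:62420125, from 68.1% ± 7.98 to 12.6% ± 7.43, a difference of -55.0 points (adjusted p = 6.38e-06, same model). The remaining named sites were chr2:23938283 and chr3:8451629 in the Uhrf1 KO and F46A lists, chr13:62420071 in the F46A list, and chr2:23940180, chr2:138395344, chr3:8451689 and chr1:150233215 in the H730A list. No site higher than in wtJ1 met the rule for naming.

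The few sites called higher than wtJ1 are named here after their values were seen. In H730A they were chr1:40195431, at 100% ± 0 against 89.1% ± 5.33 in wtJ1 (adjusted p = 0.00431), and chr10:112587346, at 85.1% ± 6.17 against 62.7% ± 6.66 (adjusted p = 0.0105), both off the amplicon template and with at most 31 calls in a library. In F46A they were chr13:4982513, at 4.91% ± 4.23, and chr4:21650915, at 6.11% ± 5.14, where wtJ1 had 0 methylated calls of 95 and of 68, which allow shares of up to 3.16 and 4.41% (adjusted p = 0.0247 and 0.0401, quasi-binomial model with limma). The count of 2 higher sites in F46A fell to 0 without F46A replicate 4, with the replicate block and with a minimum of 30 calls. Without wtJ1 replicate 2, 3 or 4 it was 1. In H730A the count of 2 fell to 0 with a minimum of 30 calls, and without position 1 and sites off the template.

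The 3 mutant genotypes shared most of their losses. Sites lower than wtJ1 in both members of a pair numbered 9098 for Uhrf1 KO and H730A, 9407 for Uhrf1 KO and F46A, and 9125 for H730A and F46A. Independent lists of these sizes would share 8764, 9062 and 8793 sites, and 20 simulations of unchanged groups against the shared wtJ1 libraries gave 0. The simulated groups were drawn at the wtJ1 level, with no change to call. This 0 therefore does not measure what the shared libraries add to the overlap of long lists. With separate pairs of wtJ1 libraries for the 2 mutants, the shared losses numbered 8017, 8554 and 7943, and 7943, 8569 and 8053 with the pairs exchanged. The lists of Uhrf1 KO and the mutants cover nearly all tested sites, which leaves little room for an overlap beyond chance.

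H730A libraries lay above Uhrf1 KO libraries in LINE1 methylation level. The difference was 2.50 percentage points (95% interval 1.46 to 3.71), or 1.51-fold, and all 4 H730A libraries lay above all 4 Uhrf1 KO libraries (exact permutation p = 0.0286). After adjustment over the 3 comparisons between mutants the p was 0.0857, which does not pass 0.05. At 0.0286, the smallest exact p, it could pass only if a second of the 3 comparisons also reached 0.0286. Site by site, 2177 of 10185 sites were higher and 80 lower in H730A than in Uhrf1 KO (quasi-binomial model with limma's moderated dispersion, adjusted p under 0.05). The count of 80 ranged from 30 to 90 when 1 library was left out. It was 207 by Fisher's exact test on summed calls, 140 with a minimum of 30 calls and 79 by limma on logit values. Without position 1 and sites off the template it was 139. With the replicate number as a block 0 sites passed and 2635 had an unadjusted p under 0.05. With calls summed per copy, 445 of 753 copies were higher and 3 lower. Among the named sites were chr2:23939238 (5.22% ± 2.19 in Uhrf1 KO, 42.8% ± 5.51 in H730A), chr1:150233242 and chr3:91127069 (5.13% ± 4.28 and 36.9% ± 8.28). The 3 copies lower in H730A, named after their values were seen, were at chr3:15028625 to 15028767 (8.51% ± 1.34 in Uhrf1 KO, 4.31% ± 1.04 in H730A), chr10:106391417 to 106391542 (4.21% ± 0.693 and 2.57% ± 0.557) and chr5:104893872 to 104894205 (2.48% ± 0.311 and 1.60% ± 0.643).

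F46A cells were close to the knockout in level. The difference from Uhrf1 KO was 0.447 points, with a 95% interval from -0.777 to 1.63 (exact permutation p = 0.400, adjusted p = 0.400), and 3 of the 4 F46A libraries lay above all Uhrf1 KO libraries. The difference was 0.0688 points without F46A replicate 4 and 0.823 points without F46A replicate 3. The quasi-binomial model with limma's moderated dispersion called 0 sites, with 1326 at an unadjusted p under 0.05. Other tools and settings called more. limma on logit values called 1 site, Fisher's exact test on summed calls 626, and the quasi-binomial model 296 with a minimum of 30 calls, 295 of them higher in F46A. Leaving out F46A replicate 3 gave 32 sites, all higher in F46A. With calls summed per copy, 0 of 753 copies were called, 53 of them at an unadjusted p under 0.05.

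F46A was lower than H730A at part of the sites. The level differed by -2.05 points (95% interval -4.34 to 0.0228), 3 of the 4 F46A libraries lay below all H730A libraries, and the difference did not pass (exact permutation p = 0.0571, adjusted p = 0.0857). The quasi-binomial model with limma's moderated dispersion called 243 sites lower and 1 higher in F46A, and 206 of 753 copies lower and 0 higher with calls summed per copy. The tools differed, with 2 sites by limma on logit values, 1407 by Fisher's exact test on summed calls, 706 in 1 fit of all 16 libraries and 0 with the replicate block. Named sites included chr1:150233242 (40.2% ± 7.22 in H730A, 8.20% ± 4.87 in F46A), chr2:23940173 (49.2% ± 3.39 and 24.0% ± 5.64), and chr2:23938293 (41.8% ± 7.13 and 18.3% ± 5.03). The 1 site higher in F46A was chr2:11122086, at 11.1% ± 3.11 against 3.64% ± 0.752 (named after its value was seen). Leaving out any 1 of the 8 libraries lowered the count of 244. It was 0 without F46A replicate 1 or 3 or H730A replicate 1, 2 or 3, 6 without H730A replicate 4, 36 without F46A replicate 4 and 137 without F46A replicate 2.

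The genotypes also differed in which CpG of the amplicon kept methylation. These position tests were added after the data were seen. The CpG sites of most copies fell on a shared template of 15 positions, counted here in bp from 1 at its most upstream CpG along the strand of the calls. In Uhrf1 KO methylation was retained mainly at positions 49, 53, 90, 103 and 110, with 9.28% ± 0.150, 8.51% ± 0.0883, 11.6% ± 0.124, 7.85% ± 0.0686 and 7.55% ± 0.156 (SD, n = 4). Positions 8 and 34 were nearly empty in the knockout, at 1.10% ± 0.0590 and 0.935% ± 0.0318, against 23.5% ± 0.509 and 17.0% ± 0.355 in wtJ1 (SD, n = 3). In H730A the highest level was at position 113, with 13.8% ± 0.938, where Uhrf1 KO had 3.07% ± 0.0523 and wtJ1 31.9% ± 0.295. H730A was higher than Uhrf1 KO at 9 of 15 positions and lower at positions 53 and 90 (exact permutation p = 0.0286 each, adjusted p = 0.0390 over 15 positions). In copies with a single unit the call at position 53 was lost (exact permutation p = 0.0857). The difference was 10.7 points at position 113 (95% interval 9.40 to 11.7), 6.40 at position 8, 5.16 at position 65, 5.03 at position 34, -0.614 at position 53 and -2.61 at position 90 (95% interval -4.10 to -0.454).

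F46A overlapped Uhrf1 KO at 11 of the 15 positions and not at the other 4. At positions 8, 34, 65 and 113 all 4 F46A libraries lay above all Uhrf1 KO libraries, by 1.57, 2.05, 2.52 and 4.12 points (exact permutation p = 0.0286 each, adjusted p = 0.107 over 15 positions, which does not pass). With only 4 of 15 positions at 0.0286, the smallest possible p, the adjusted p could not pass. F46A lay below H730A without overlap at 7 positions, with the largest difference of -6.61 points at position 113 (exact permutation p = 0.0286 each, adjusted p = 0.0612). With 7 of 15 positions at the smallest p, this could not pass either. All 3 mutants were lower than wtJ1 at 14 of the 15 positions (exact permutation p = 0.0286 each, adjusted p = 0.0306). The exception, position 1, had 35 sites and at most 0.234% in any genotype.

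**Figure D3:**
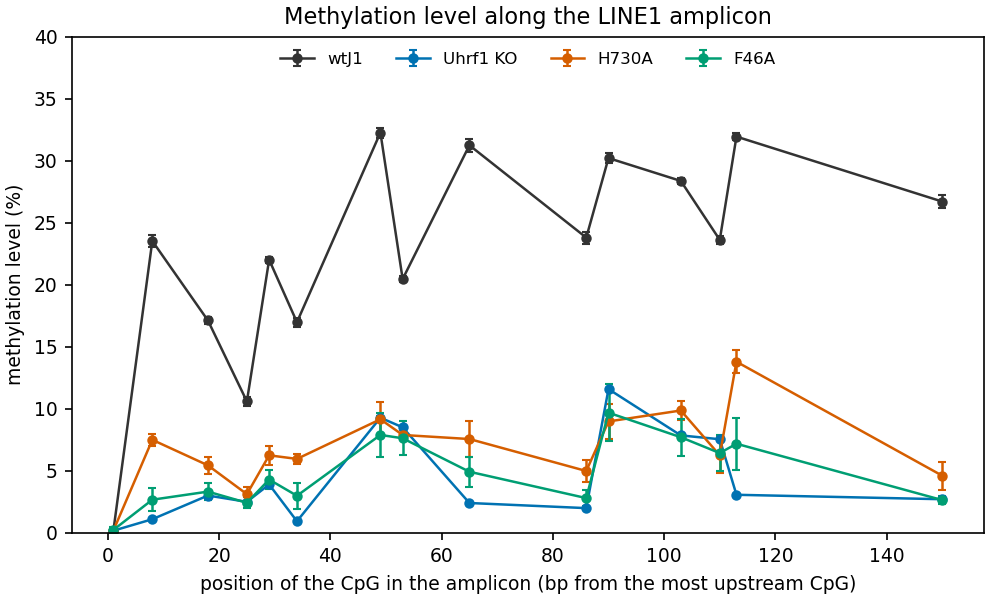
Methylation level in percent (y axis) at the 15 CpG positions of the LINE1 amplicon, in bp from the most upstream CpG (x axis), for the 4 genotypes. Points are means and bars are SD (n = 3 for wtJ1, n = 4 for the others), and Uhrf1 KO peaks at position 90 with 11.6%, and H730A at position 113 with 13.8%.

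LINE1 copies lost methylation wherever they lay. All 214 copies inside genes and all 99 on the X chromosome were lower than wtJ1 in each mutant by the test on summed calls. Of the 6 gene lists fixed beforehand, 4 had 0 tested sites, namely DNA methylation machinery (21 genes), heterochromatin and retroelement silencing (25), pluripotency (28) and germline genes (30). Of 46 imprinted genes only Snrpn, a paternally expressed gene, held a copy, at chr7:60162996 to 60163138 (also in the span of Snhg14), which went from 25.4% ± 1.55 in wtJ1 (SD, n = 3) to 4.69% ± 0.667 in Uhrf1 KO, 6.85% ± 2.68 in H730A and 4.90% ± 1.79 in F46A (SD, n = 4). Of 51 very long neuronal or fragile-site genes, 12 held 18 copies with 236 sites, and all 18 were lower in each mutant. Lrp1b, a lipoprotein receptor family member, went from 24.8% ± 0.112 in wtJ1 to 5.00% ± 0.273 in Uhrf1 KO, 7.25% ± 0.749 in H730A and 5.49% ± 1.24 in F46A. Il1rapl1, an X-linked synaptic receptor gene, went from 20.8% ± 1.17 to 3.80% ± 0.319, 6.93% ± 0.472 and 4.96% ± 0.609. Against Uhrf1 KO, 9 of these 18 copies were higher in H730A and 0 were called in F46A. The Lrp1b values rest mainly on the copy at chr2:42083590 to 42083732, with 99227 calls in wtJ1. The copy at chr2:42214470 to 42214612 had 3794. How reads of near-identical copies were placed is not known, so the values may not be those of the Lrp1b locus alone.

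The size of the loss did not pass a test of difference between locations. In 12 tests (4 classes by 3 mutants) the smallest adjusted p was 0.0686. Too few of the 12 reached 0.0286, the smallest exact permutation p, for any to pass after adjustment. Inside genes the wild-type level was 24.4% ± 0.314 against 25.1% ± 0.371 elsewhere (SD, n = 3), and the loss in Uhrf1 KO was smaller by 0.564 points (exact permutation p = 0.0286, adjusted p = 0.0686). In the very long genes the wild-type level was 23.9% ± 0.203 against 24.9% ± 0.360 elsewhere, and the loss was smaller by 0.839 points in Uhrf1 KO, 0.777 in H730A and 0.861 in F46A (exact permutation p = 0.0286 each, adjusted p = 0.0686). Uhrf1 KO was at 4.80% ± 0.227 there and 4.95% ± 0.0693 elsewhere. A lower wild-type level leaves fewer points to lose, and losses as a share of it were not tested. Lrp1b held 419991 calls of this class and Il1rapl1, the next gene, 63606. On the X chromosome the change in Uhrf1 KO minus that on other chromosomes was -0.289 points, a nominally larger loss (exact permutation p = 0.0857, adjusted p = 0.147).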

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

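The weighing tests in this part were all chosen after the results were seen. Of 51 sets of 4 libraries examined for a library far from its group, 3 had one, and chance gives about 2.55. H730A replicate 4 was low at amplicon position 8 (6.81%, the others between 7.65 and 7.80%) and at position 34 (5.31%, the others between 6.11 and 6.22%). Uhrf1 KO replicate 3 was high at position 34 (0.982%, the others between 0.917 and 0.922%).

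H730A libraries lay above Uhrf1 KO libraries in level, though not at every CpG position. DNA of wild-type cells mixed into knockout-like libraries would raise each position, but position 90 was lower by -2.61 points. Incomplete conversion in H730A at the same rate across positions would raise all positions alike, but the difference reached 10.7 points at position 113. Conversion that varies by position is left open. Another mix of amplified copies would shrink with equal weight per copy, but the difference was then 2.80 points. A hypothesis that stays open, untested here, is that H730A protein may keep part of its activity at some CpG contexts, and PCR that favours methylated molecules at some copies is open as well. Whether libraries came from separate clones or cultures is not given, so a difference between clones or cultures cannot be told apart from the genotype.

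The 4 F46A libraries differed from each other in profile as well as in level. Conversion that differs between them would put 1 library of a pair above the other throughout and by no more than its lowest position other than position 1 allows, and 4 of the 6 pairs departed from this by more than counting error. For example, replicate 1 exceeded replicate 2 by 4.15 points at position 90 and was below it by -2.58 points at position 113. Mixing of DNA like the other genotypes would keep each library within their range, and 2 of the 4 libraries, replicates 2 and 3, fell below all other genotypes at some position. Single libraries set against counting error exclude neither, so conversion and mixing cannot be told apart from differences between the cultures.

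Uhrf1 KO kept its remaining methylation mainly at positions 49, 53, 90, 103 and 110. A base read as C whatever its methylation would set a floor for all genotypes. If it supplied the whole knockout level, no genotype would lie below that level. H730A lay below Uhrf1 KO at position 90 by -2.61 points, past the test. A lower floor that supplies part of the 11.6% in Uhrf1 KO there stays open. At position 90 H730A replicate 4 was at 7.64% and F46A replicate 2 at 6.74%. Of the other 4 positions, 0 had H730A below Uhrf1 KO past the test both in all copies and in copies with a single unit. With the H730A and F46A libraries pooled, 6, 7, 1 and 6 of 8 lay below every Uhrf1 KO library at positions 49, 53, 103 and 110 (exact permutation p = 0.366, 0.137, 0.277 and 0.113). A test of means cannot decide this, since libraries above the knockout level offset those below it. At these 4 positions such a base cannot be told apart from methylation. A few copies with such a base would leave the median copy low, but the lowest of the 5 medians over amplicon units was 7.56%, above the level of every other position. Methylation placed there without UHRF1, with a preference for some flanking sequences, is a candidate explanation that was not tested.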

How the results depend on the processing

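Tests with calls summed per copy, equal weights, all listed sites, the reduced template and wtJ1 counted as 3 were chosen after the data were seen. The 3 level differences from wtJ1 and that between F46A and Uhrf1 KO kept their direction in all alternatives run, and tests able to reach 0.05 stayed on the same side of it. For H730A against Uhrf1 KO and F46A against H730A the adjusted p fell from 0.0857 to 0.0429 with unweighted sites (2.76 and -2.33 points), thinning to 10 calls (2.67 and -2.25), equal weight per copy (2.80 and -2.39), equal weight per position (2.33 and -1.91) and all listed sites (2.56 and -2.10). For H730A against Uhrf1 KO the exact permutation p with pooled calls was already 0.0286, the smallest possible. Its adjusted p fell because F46A and H730A no longer overlapped. With pooled calls F46A replicate 4 (6.53%) lay above H730A replicate 4 (6.51%), and with unweighted sites below it (6.59 against 6.80%). Why the weighting moved these libraries was not tested. Site counts for Uhrf1 KO, H730A and F46A against wtJ1 fell with fewer sites tested, to 1779, 1780 and 1777 of 1784 (minimum of 100 calls), 628, 598 and 628 of 650 (1 per 1000 bp) and 753 each (copies), and with adjusted p 0.01 and a 25-point minimum together to 2863, 1590 and 2624. Counting wtJ1 as 3 gave 9584, 9283 and 9606.

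For H730A against Uhrf1 KO the count was 897 (minimum of 100 calls), 16 (adjusted p 0.01 and 25 points), 169 (1 per 1000 bp) and 448 (copies). For F46A against Uhrf1 KO it rose from 0 to 296 and 337 (minimum of 30 and 100), 213 (all 16 libraries), 1 (limma), 626 (Fisher), 8 (1 per 1000 bp), 171 (reduced template) and 0 to 32 (libraries left out). For F46A against H730A it was 696 and 434 (minimum of 30 and 100), 706 (all 16 libraries), 2 (limma), 1407 (Fisher), 0 (adjusted p 0.01 and 25 points), 11 (1 per 1000 bp), 772 (reduced template) and 0 to 137 (libraries left out). The causes were not tested. At position 53 the p for H730A against Uhrf1 KO was 0.0857 in copies with a single unit, by exact permutation.

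Same-numbered replicates did not deviate together over copies. Their 24 correlations over copies ran from -0.0916 to 0.115, and 4 of 16 libraries were closest to their own number. The numbers therefore do not pair the samples in their profile over copies, while pairing in level or by amplicon position was not tested. Replicate 3 had the highest level in wtJ1, Uhrf1 KO and H730A and the lowest in F46A. With the replicate block the counts for H730A against Uhrf1 KO and F46A against H730A were 0 and 0.

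Other splits of the 8 libraries were counted after the result was seen. In 5 comparisons 1 of 35 splits, the real one, gave as many sites (9591, 9309, 9625, 2257 and 244), and the highest other split gave 0. Chance can be excluded only at this share, which is not adjusted over comparisons, and mixed groups carry the genotype difference as spread, which lowers their counts. For F46A against Uhrf1 KO the real count was 0, the highest other was 0 and 35 of 35 splits reach it by definition, so this decides nothing. Simulated changes of 8 to 10 points in 300 of 10185 sites were mostly missed. They were set for Uhrf1 KO against wtJ1 and H730A against Uhrf1 KO, and F46A against Uhrf1 KO was not simulated.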

Other observations

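The most methylated copies included 3 neighbours on chromosome 2 outside annotated genes, at 23938188 to 23938330, 23939133 to 23939275 and 23940078 to 23940220. Their levels were 49.3% ± 2.13, 49.9% ± 5.04 and 58.2% ± 1.60 in wtJ1 (SD, n = 3), 10.4% ± 1.16, 8.81% ± 1.72 and 9.27% ± 2.25 in Uhrf1 KO, 22.8% ± 3.05, 23.6% ± 2.87 and 23.8% ± 2.84 in H730A, and 12.9% ± 1.93, 12.1% ± 2.83 and 12.6% ± 3.48 in F46A (SD, n = 4). The highest copy in wild type was at chr1:150233137 to 150233279, with 59.5% ± 1.82 in wtJ1, 8.93% ± 3.02 in Uhrf1 KO, 24.8% ± 3.50 in H730A and 8.54% ± 2.25 in F46A. The copy at chr13:62420030 to 62420172 was also above 50% in wtJ1, at 51.1% ± 6.29, but H730A had only 9.64% ± 5.81 there, near Uhrf1 KO at 8.18% ± 1.40. These copies were picked by their values, and the differences between them were not tested.

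Some copies held the amplicon several times in a row. Of 753 copies, 79 had more than 1 unit, and 60 of 97 distances between neighbouring units were 212 bp. The 5' ends of mouse LINE1 elements carry tandem repeats called monomers. Only 2 of 10185 sites stayed at 60% or more in every genotype. The site chr1:40195431 was at 89.1% ± 5.33 in wtJ1, 82.8% ± 9.40 in Uhrf1 KO, 100% ± 0 in H730A and 81.0% ± 6.79 in F46A. The site chr10:112587346 was at 62.7% ± 6.66, 79.1% ± 16.1, 85.1% ± 6.17 and 76.5% ± 11.2. Both had between 12 and 31 calls in a library.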
